A study of Mus musculus with 4 samples.

How the data were processed

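Single-cell 5' gene expression libraries and B cell V(D)J libraries were made from MC38 tumours, a mouse colon carcinoma line grown under the skin of C57BL/6 females aged 12 to 16 weeks. Recipients either carried floxed Prdm1 alleles alone (control) or with a cre recombinase active in B cells (knockout). Per the labels' protocols, tumours of 11 recipients per genotype were taken 18 days after inoculation and pooled. Viable B220+ cells and CD138+ cells were sorted and combined in proportions that the sources used here do not give, so the mixing can set the share of any cell type. The target was 1400 cells per library, with 24000 reads per cell for expression and 6000 for V(D)J. There was 1 expression library and 1 V(D)J library per genotype. The deposited files of the 2 genotypes carry different date stamps, so library batch and genotype cannot be told apart.

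The deposited expression matrices hold UMI counts per gene and barcode, made with Cell Ranger 6.0.0 per the file headers, and on GRCm38 (mm10) per the submitters' processing notes. They list barcodes that Cell Ranger had called as cells and 32285 genes. The deposited V(D)J tables hold contigs with their read counts and UMI counts, V, D, J and constant gene calls, and region sequences. All contigs in them were full length and productive. Gene symbols came from the matrices. Positions came from the RefSeq annotation of GRCm38.p6. Of the fixed gene list members, 3 had no unique symbol in the matrices (Mx1, which was not found, and Ddit3 and Aldoa, whose symbols each belong to more than 1 gene) and were not used.

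Barcodes with under 200 genes or over 10% mitochondrial UMIs were removed. Doublets were called per library with Scrublet as run in Scanpy 1.11.5, and barcodes with 2 distinct heavy-chain CDR3 sequences were also removed. Scrublet marked 8 of 816 control and 3 of 897 knockout barcodes, and 6 knockout barcodes carried 2 heavy chains. The remaining 798 control and 865 knockout cells were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, immunoglobulin genes were left out, and 2000 variable genes, 30 principal components and 15 neighbours were used with Leiden clustering (leidenalg 0.10.2 installed, igraph implementation) at resolution 1. Clusters were named from 15 marker lists. A cluster took a name when that list had the highest mean log2 level over the other cells and reached at least 1, at least 3 of its markers were detected in 10% or more of the cells, at least 1 was among the cluster's leading 25 genes, and no other list had more markers there. The marker lists were fixed before the data were examined, but this naming rule was set after the clusters had been seen. It left 4 of 17 clusters unnamed, and 6 lists named no cluster (germinal centre B cell, neutrophil, erythroid, platelet, fibroblast or endothelial, and tumour or epithelial cell).

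UMI counts were summed per class and genotype and expressed as counts per 1000000 UMIs (CPM) of that class. With 1 library per genotype there was no test, no p-value and no standard error. A CPM carries an exact Poisson interval, a ratio of 2 CPM values an exact conditional binomial interval, and a share a Clopper-Pearson interval, all at 95%. All of these cover counting error only, and not the spread between mice, sorts or libraries. A count of 0 allows up to 3 counts of the total. In each of 20 gene lists, members with at least 10 UMIs over both libraries entered a median log2 ratio of knockout over control, with a count of 0 set to 3. Its interval came from Poisson redraws of the counts, and its percentile from 10000 random lists of the same size matched on mean level. Medians of all genes with at least 50 UMIs moved by -0.07 in the B cell class and 0.00 in the NK cell class on the log2 scale. NK-like cells, in which that cre is not expected to act, served as a reference for differences between whole libraries.

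The named genes followed a rule fixed before the data were examined. In each class with at least 50 cells in both libraries, genes with at least 50 UMIs were ranked by the bound of the ratio's interval nearest to 1, and the first 12 higher and the first 12 lower are named. Immunoglobulin, T cell receptor, mitochondrial, ribosomal protein and predicted genes were left out of that ranking. Up to 4 list members with the most UMIs, Prdm1, every isotype, the 3 commonest IGHV genes and the 3 biggest clones per library are also named where the text describes them. Values of some genes are not reported here. Pax5, the sizes of the 2 large B-like clusters and the Jchain cut of 5 UMIs were singled out after the values had been seen. Shares of cells with a UMI were compared after each cell was thinned to 1500 UMIs.

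A cell's isotype was that of its heavy-chain contig with the most UMIs. A clone shared IGHV gene, IGHJ gene and CDR3 nucleotides within a genotype. Clone shares were compared after 1000 random draws of as many knockout cells as control cells. No genome sequence was used, so the germline sequence of a V gene was taken as its commonest framework 1 to framework 3 sequence among IgM and IgD cells of both libraries, for the 25 V genes with at least 5 such cells. That sequence was carried by a median of 77.8% of those cells, and by 25.8% at the lowest. A cell with 2 or more base differences from it was called mutated.

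The ratio and list steps were tested on simulated counts for the comparison of B-like cells, over 4371 genes. Intervals lay on the right side of 1 for 100% of genes raised 4-fold, 98% of genes raised 2-fold, 84% of genes lowered to 0.5 and 100% of genes lowered to 0.25, with 50 genes simulated at each size, and they held 1 for 95.9% of 4171 unchanged genes. All 12 genes named higher and all 12 named lower had been simulated so. Of 100 lists of 15 unchanged genes, 96 lay between percentiles 2.5 and 97.5. The simulated class totals were Poisson draws, made for each gene on its own. They held no uneven counts between cells and no genes that move together, so they do not check the intervals or lists against either. Alternatives covered barcode filters, doublets, clustering resolution, immunoglobulin genes in the clustering, classes assigned cell by cell, scaling, list minimums, clone definitions and mutation cut-offs. Alternatives chosen after the data had been seen were values within the 2 large B-like clusters, V(D)J shares within the B cell class, values without the cell holding the most UMIs of a gene, and a germline sequence inferred with each clone counted once. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.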

Results

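Expression and B cell receptor sequences were measured in single B220+ and CD138+ cells sorted from MC38 tumours of control mice and of mice lacking Prdm1 in the B lineage. Prdm1 encodes Blimp-1, a transcription factor required for plasma cell differentiation. The control expression library held 816 barcodes and 6976374 UMIs, with a median of 5851 UMIs per barcode. The knockout library held 897 barcodes and 5463434 UMIs, with a median of 3966. The study asked how blocking the plasma cell fate alters antigen presentation by B cells, and the comparisons below set the genotypes side by side in cell makeup, expression of B-like cells and B cell receptors. Each genotype is 1 library from pooled mice, so no difference has a replicate check and every interval is a 95% interval for counting error only.

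The targeted gene, Prdm1 (ENSMUSG00000038151, chromosome 10, positions 44437174 to 44528558, GRCm38), was found at 43.1 CPM in the control plasma-like cells, from 43 UMIs. In the B-like cells it had 1 UMI in the control (1.08 CPM, interval 0.0274 to 6.02) and 16 UMIs in the knockout (15.9 CPM, 9.09 to 25.8), a ratio of 14.7 (2.28 to 617). All 16 knockout UMIs came from the cluster led by Fcrl5 described below. That cluster held 58.5% of knockout but 20.5% of control B-like cells, so the ratio of 14.7 also carries this difference in makeup. NK-like cells held Prdm1 at 7.58 CPM in the control and 8.18 CPM in the knockout. After thinning to 1500 UMIs, 0 of 235 control and 3 of 277 knockout B-like cells kept a Prdm1 UMI (1.08%, 0.224 to 3.13%), and after thinning to 1000 UMIs 0.418% and 2.47% did, with overlapping intervals both times. Unthinned, the shares were 0.418% (0.0106 to 2.31%) and 4.53% (2.43 to 7.62%), with intervals apart although the control cells were the deeper ones, at median depths of 3055 and 2713 UMIs. NK-like cells with a Prdm1 UMI were 0.658% and 3.31% at 1500 UMIs, 1.97% and 0.823% at 1000 UMIs, and 7.24% and 6.53% unthinned. The labels do not say which exons were floxed, and 5' reads can lie outside them. The Prdm1 level therefore does not check the genotype label.

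Plasma-like cells were found only in the control library. Their cluster was led by Tnfrsf17, the BCMA receptor, Jchain, the immunoglobulin joining chain, and Derl3, and it held 47 of 798 control cells (5.89%, 4.36 to 7.76%) and 0 of 865 knockout cells, which allows a share of up to 0.347%. Jchain (chromosome 5, positions 88519809 to 88527897) reached a median of 793 UMIs per cell in these 47 cells, with a lowest value of 291. No knockout barcode, filtered or not, held 100 or more Jchain UMIs. Igha and Igkc stood at 16161 and 21219 CPM in the control plasma-like cells. Over all kept cells, Igha was 2347 CPM in the control and 65.0 CPM in the knockout, and Igkc was 3276 and 359 CPM. The sort combined CD138+ with B220+ cells in unstated proportions, which can set this share.

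B-like cells made up 29.9% of the control cells (239 of 798, 26.8 to 33.3%) and 33.2% of the knockout cells (287 of 865, 30.0 to 36.4%), and these intervals overlap. NK-like cells were 19.0% of the control (16.4 to 21.9%) and 28.3% of the knockout (25.3 to 31.5%). Macrophage- or monocyte-like cells were 11.9% (9.74 to 14.4%) and 5.20% (3.82 to 6.90%). T-like cells were 4.26% and 4.97%, plasmacytoid dendritic-like cells 4.64% and 4.39%, mast cell- or basophil-like cells 4.26% and 5.20%, conventional dendritic-like cells 0.251% and 0.578%, and cycling cells 3.38% and 4.39%. The T-like class joined 2 clusters that moved in opposite directions. The cluster led by Tcrg-V1 held 8 of 798 control cells (0.434 to 1.97%) and 31 of 865 knockout cells (3.58%, 2.45 to 5.05%). Those intervals lay apart. The cluster led by Tff1 held 3.26% of the control (2.14 to 4.74%) and 1.39% of the knockout cells (0.719 to 2.41%). Unnamed clusters held 16.4% of the control and 13.8% of the knockout cells. Among them, a cluster led by Pmp22, Inhba and Gpnmb held 8.90% of the control and 1.97% of the knockout cells. An unnamed cluster led by Sema6d, Tnfsf10 and Itga1 held 0.376% and 6.01%, so almost all of its cells came from the knockout library. Its best-scoring marker list was that of NK cells, but it did not meet the naming rule, and whether it reflects a cell type or the library was left open. Counting it as NK-like would widen the gap in NK-like shares given above. The sort and the depth gap between the libraries can set all of these shares. NK-like and macrophage-like shares also depended on how clusters were drawn: without a barcode filter, NK-like cells were 95 of 808 in the control and 146 of 888 in the knockout, and at Leiden resolution 0.5 macrophage- or monocyte-like cells were 167 of 798 and 62 of 865.

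**Figure D1:**
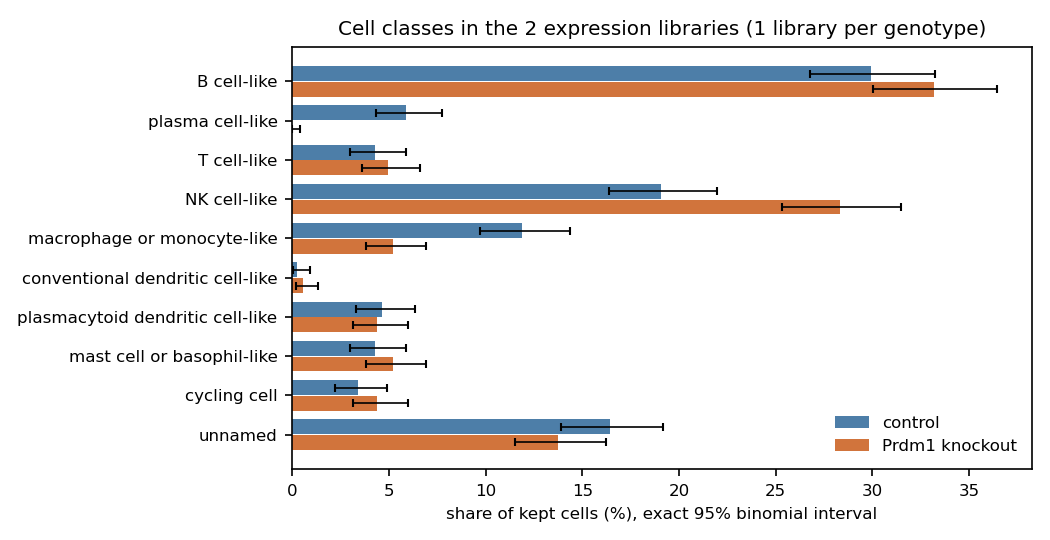
Share of kept cells (%, x axis) in each cell class for the control and the Prdm1 knockout expression library, with exact 95% binomial intervals as error bars. Plasma-like cells are at 5.89% in the control and 0% in the knockout, while B-like cells are at 29.9% and 33.2%.

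The B-like cells of the genotypes fell mainly into different clusters. A cluster led by Fcer2a, the CD23 receptor of follicular B cells, with Vpreb3 and Ebf1, held 182 of 239 control B-like cells (76.2%, 70.2 to 81.4%) and 110 of 287 knockout B-like cells (38.3%, 32.7 to 44.2%). A cluster led by Fcrl5, an Fc receptor-like gene, with Ms4a1, which encodes CD20, and Cd22 held 49 control cells (20.5%, 15.6 to 26.2%) and 168 knockout cells (58.5%, 52.6 to 64.3%). Another, small cluster with the interferon-induced Ifit3 and Ifi208 among its leading genes held 8 and 9 cells. Cells of the Fcrl5 cluster had a median of 5816 UMIs in the control and 3046 in the knockout. Values over all B-like cells can therefore mix a difference in makeup with differences inside the clusters. List medians are given for all B-like cells and then within the Fcer2a and the Fcrl5 cluster, in that order.

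Transcripts of MHC class II presentation had a median slightly below the control over all B-like cells, while the interval of the list median included 0 within each large cluster. Of 17 measured list members, 4 were higher and 13 lower, with a median log2 ratio of -0.16 (-0.24 to -0.12) at percentile 3.77 of random lists. H2-Ab1 had a ratio of 0.854 (0.816 to 0.894), H2-Eb1 0.890, H2-Aa 0.895 and Cd74, the invariant chain, 0.919. The list median was -0.09 (-0.18 to 0.02) in the Fcer2a cluster and -0.02 (-0.15 to 0.05) in the Fcrl5 cluster. In NK-like cells it was -0.18 (-0.42 to 0.04, percentile 4.24), with 9 of 13 measured members lower. Before thinning, 21.7% of control NK-like but 99.6% of control B-like cells had an H2-Ab1 UMI, so NK-like cells were a weak reference here. Over all cells outside the B-like, plasma-like and cycling classes, whose makeup also differed, the list median was -0.46 (-0.69 to -0.35). A difference between whole libraries therefore stays open for this list. The MHC class I list (16 measured, 11 higher) had a median of 0.06 at percentile 90.1, with H2-K1 at 1.13, H2-D1 at 1.09, B2m at 1.12 and the immunoproteasome subunit Psmb8 at 0.924. Its median was 0.14 (-0.001 to 0.24) in the Fcer2a cluster. In the Fcrl5 cluster it was -0.18 (-0.32 to -0.07), with 12 of 16 members lower, at percentile 8.25 of random lists. Of 12 costimulation genes, 6 were higher and 6 lower, with a median of -0.07, against 0.28 and -0.15 within the clusters. In that list Cd40, the receptor for T cell help, was at 0.460 (0.332 to 0.630), Cd48 at 0.789, Cd83 at 0.902 and Cd86 at 1.45 (1.03 to 2.08). Within the clusters led by Fcer2a and Fcrl5, Cd40 was at 0.683 (0.432 to 1.05) and 0.418 (0.248 to 0.697). After thinning to 1500 UMIs, 19.6% of control (14.7 to 25.2%) and 11.2% of knockout B-like cells (7.73 to 15.5%) had a Cd40 UMI, with overlapping intervals. At 1000 UMIs the shares were 13.4% (9.34 to 18.4%) and 4.95% (2.73 to 8.16%), with intervals apart.

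Secretory genes showed no clear difference as a list, since the interval of its median included 0. The plasma cell and secretion list had 10 of 15 measured members higher and a median log2 ratio of 0.18 (-0.02 to 0.34) at percentile 99.4, with -0.05 in the Fcer2a cluster and 0.13 in the Fcrl5 cluster. Its members included Mzb1 at 1.35 (1.22 to 1.499), Ssr4 at 1.13, Sec61b at 1.003 and Sec11c at 1.002. Jchain was at 10.0 (5.41 to 20.6), but 80 of its 120 knockout UMIs lay in 1 cell, and without the top cell of each library the ratio was 4.60. Few cells carried this, since 4 of 287 knockout and 0 of 239 control B-like cells held 5 or more Jchain UMIs. After thinning to 1500 UMIs, 1.28% of control (0.264 to 3.69%) and 1.81% of knockout B-like cells (0.589 to 4.16%) had a Jchain UMI. The unfolded protein response list had 12 of 17 members higher and a median of 0.22 (0.04 to 0.36) at percentile 99.9, against -0.20 in NK-like cells. Within the clusters its median was 0.08 (-0.13 to 0.39) and 0.11 (-0.07 to 0.33), so both intervals included 0. In it, Pdia4 was at 1.49, Hsp90b1 at 1.36, Hspa5, the main endoplasmic reticulum chaperone, at 1.25 and Pdia3 at 1.17.

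Several lists of B cell subsets had other medians within the clusters than over all B-like cells. The follicular and naive list had 12 of 14 members lower and a median of -0.37 at percentile 0. Its median was -0.04 (-0.15 to 0.12) in the Fcer2a cluster but 0.26 (0.09 to 0.50) in the Fcrl5 cluster. The B1 and marginal zone list had 8 of 11 members higher and a median of 0.43 at percentile 100, against -0.14 and 0.02 within those clusters. The memory and atypical list had 10 of 15 members higher and a median of 0.27 at percentile 99.8, against 0.35 (-0.21 to 0.64) and -0.38 (-0.66 to -0.04). In the naive list Klf2, a regulator of lymphocyte trafficking, was at 0.690, Btg1 at 0.830, Fcmr at 0.879 and Ighm at 1.14. In the other lists Plac8 was at 2.18 (2.01 to 2.36), but at 1.24 (0.996 to 1.53) and 1.49 within the clusters, and Anxa2 was at 1.48, Ahnak at 0.775, Zbtb20 at 1.55, Itgb1 at 1.30, Hhex at 0.996 and Ccr6 at 0.679. The 8 measured germinal centre genes split evenly, with a median of -0.21 at percentile 28.4, against 0.36 and -0.18 within the clusters. Of these, Bcl6, the master regulator of that programme, was at 1.23 (0.638 to 2.40), Neil1 at 1.43, Cd38 at 1.05 and Fas at 0.588.

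Interferon-response genes were higher over all knockout B-like cells, with 17 of 20 members higher and a median of 0.54 (0.32 to 0.72) at percentile 100. The medians within the Fcer2a and Fcrl5 clusters were 0.17 (-0.02 to 0.71) and 0.16 (-0.16 to 0.53), and the NK-like cells stood at -0.01. Over all cells outside the B-like, plasma-like and cycling classes, whose makeup also differed, the median was -0.51 (-0.56 to -0.41), with 15 of 20 members lower. Usp18, which dampens interferon signalling, was at 3.45 (1.96 to 6.41). Within the Fcer2a and Fcrl5 clusters it was at 4.62 (1.05 to 27.7) and 3.81. The Fcer2a value came from only 3 control and 7 knockout UMIs. The ubiquitin-like modifier Isg15 was at 2.94 (2.22 to 3.92), and at 1.80 (0.685 to 4.67) and 1.97 within them. Its Fcer2a value came from 11 control and 10 knockout UMIs, and that interval included 1. The guanylate-binding Gbp2 was at 4.37 (2.52 to 8.02), with 1.98 (0.455 to 8.60) and 3.05 within them, Ly6a at 1.29, Ifi27l2a at 1.005 and Irf1 at 0.803.

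Immediate early genes were lower over all knockout B-like cells, with 11 of 14 members lower and a median of -0.40 (-0.57 to -0.28) at percentile 0.04. The Fcer2a cluster had a list median of -0.08 (-0.44 to 0.08) and 7 of 13 members lower, with Fos at 0.672 (0.535 to 0.839) and Junb at 0.781 (0.676 to 0.899) there, while the Fcrl5 cluster had a median of -0.38 (-0.57 to -0.12). The transcription factors Fos, Junb, Nr4a1 and Ier2 were at 0.501 (0.422 to 0.594), 0.546 (0.490 to 0.608), 0.263 (0.126 to 0.508) and 0.705, and the inhibitor Nfkbia at 0.863. NK-like cells moved the same way, with a list median of -0.26 and Fos at 0.753, Junb at 0.767 and Nr4a1 at 0.700. Over all cells outside the B-like, plasma-like and cycling classes, whose makeup also differed, the list median was 0.17 (0.02 to 0.27). There 11 of 17 members were higher, so the list as a whole did not fall there. Fos did, at 0.616 (0.561 to 0.677), while Junb was at 1.003 and Nr4a1 at 0.856 (0.695 to 1.05). A difference between whole libraries therefore stays open for these genes. The homing list had 12 of 16 members lower and a median of -0.40 at percentile 0.02, with -0.07 in the Fcer2a cluster and -0.47 in the Fcrl5 cluster. Its lymph node homing receptor Ccr7 was at 0.707, Itgb7 at 0.707 and Itga4 at 0.867. The cell cycle list had 8 of 10 members lower and a median of -0.38, close to the -0.40 of NK-like cells and against -0.15 and -0.72 within the clusters, with Hmgb2 at 0.647, Tubb5 at 0.894, Pcna at 0.903 and Mcm6 at 0.940.

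The B cell receptor signalling list had 9 of 23 members higher and a median of -0.06 at percentile 41.4, against 0.05 and 0.14 within the clusters. Cd79a and Cd79b, the receptor's signalling chains, were at 0.932 and 0.962 and the phosphatase Ptpn6 at 1.19. The B cell transcription factor list had 15 of 18 members lower and a median of -0.15, with Ebf1 at 0.743, Klf2 at 0.690, Mef2c at 0.768 and Foxp1 at 0.943. Within the clusters that median was -0.10 and 0.19. Pax5, which maintains B cell identity, was at 0.455 (0.314 to 0.652), with 0.290 in the Fcer2a cluster and 1.002 in the Fcrl5 cluster.

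Over all B-like cells the remaining lists lay within the range of the random lists, but glycolysis genes were lower within the Fcrl5 cluster. The cytokine and regulatory list had a median of -0.19 at percentile 18.8, against -0.12 and -0.17 within the clusters, with Ltb at 0.885, Tgfb1 at 0.9502 and Cd1d1 at 1.09. Glycolysis genes had a median of -0.10 at percentile 23.96, against 0.08 in the Fcer2a cluster and -0.52 (-0.65 to -0.26, percentile 0.06, 10 of 12 lower) in the Fcrl5 cluster, with Gpi1 at 1.18, Gapdh at 0.896, Pkm at 0.916 and Ldha at 0.942. Oxidative phosphorylation genes had a median of -0.07, against -0.06 and -0.17 within the clusters, with Cox4i1 at 1.07, Cox6c at 0.889, Atp5b at 1.09 and Atp5e at 0.955. Survival genes had a median of -0.12, against -0.16 in the Fcer2a cluster and -0.43 (-0.68 to -0.06, percentile 0.98, 8 of 13 lower) in the Fcrl5 cluster, with Mcl1 at 0.990, Bax at 0.807, Tnfrsf13b at 0.983 and the BAFF receptor Tnfrsf13c at 0.750. Over all cells outside the B-like, plasma-like and cycling classes, whose makeup also differed, the glycolysis median was -0.52 (-0.56 to -0.44). There 12 of 14 glycolysis members were lower, and the survival median was -0.24 (-0.34 to -0.12), with 12 of 15 lower. In NK-like cells these medians were -0.04 and -0.08. Lower glycolysis and survival medians were therefore not particular to the Fcrl5 cluster. The dissociation and heat stress list had a median of 0.05 at percentile 82.8, against 0.32 (-0.04 to 0.51, percentile 99.96) and -0.13 within the clusters, with Hspa8 at 1.504, Hsp90ab1 at 1.04 and Zfp36 at 0.739, and its median in NK-like cells was -0.14.

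**Figure D2:**
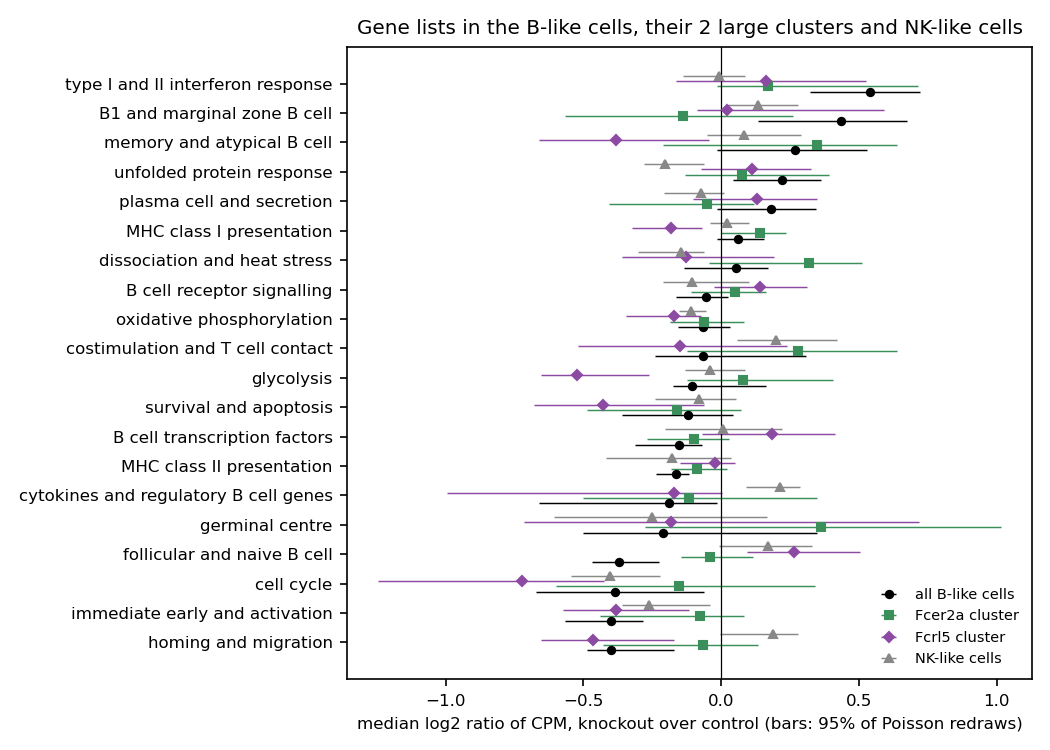
Median log2 ratio of CPM, knockout over control (x axis), of each fixed gene list (y axis) in all B-like cells, in the Fcer2a and Fcrl5 clusters and in NK-like cells, with bars spanning 95% of Poisson redraws. The follicular and naive list lies at -0.37 over all B-like cells but at -0.04 and 0.26 within the clusters, and the interferon list at 0.54 against 0.17 and 0.16.

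Of the 12 genes ranked highest in knockout B-like cells, 4 had most of their knockout UMIs in 1 cell. All 202 UMIs of Hbb-bs, a haemoglobin chain, lay in 1 cell, as did 56 of 61 of the granzyme gene Gzmf, 43 of 61 of Spp1 and 80 of 120 of Jchain. Gzmc was at 22.8 (10.2 to 63.2), with 65 of its 149 knockout UMIs in 1 cell, and at 15.4 without the top cell of each library. It had a UMI in 68 of 287 knockout and 6 of 239 control B-like cells, and was abundant in NK-like cells (a UMI in 58.6% of control and 63.3% of knockout cells). After thinning, Gzmc was found in 14.1% of knockout and 0.851% of control B-like cells. The calcium-regulated factor Nfatc1 was at 3.05 (2.22 to 4.25), with 1.89 and 2.85 in the Fcer2a and Fcrl5 clusters and 0.896 in NK-like cells. The calcium-binding gene S100a6 was at 2.76 (2.36 to 3.24) over all B-like cells but at 0.839 in the Fcer2a and 1.74 in the Fcrl5 cluster. The galectin gene Lgals3 was at 2.69 (1.85 to 3.97), with 3.96 and 1.57 in those clusters. Gbp2, Isg15, Plac8 and Usp18, described above, complete the 12.

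Among the 12 ranked lowest, the chemokine gene Ccl4 was at 0.0571 (0.0358 to 0.0871), but 365 of its 370 control UMIs lay in 1 cell. Fcer2a was at 0.361 (0.290 to 0.446) and Vpreb3 at 0.492 over all B-like cells, and at 0.735 and 0.963 within the Fcer2a cluster, which both genes define. Pxdc1 was at 0.264 (0.155 to 0.435), Lmo4 at 0.314, Kmo, an enzyme of tryptophan breakdown, at 0.325, the transforming growth factor inhibitor Smad7 at 0.328 and the interleukin receptor gene Il21r at 0.427. Within the Fcer2a and Fcrl5 clusters, Pxdc1 was at 0.413 and 0.877 (0.223 to 4.09), Lmo4 at 0.132 and 0.251, Kmo at 0.609 and 0.251, Smad7 at 0.638 and 0.251 and Il21r at 0.651 and 0.388. Of the 73 control UMIs of Pxdc1, 67 lay in the Fcer2a cluster. Cd40, Fos, Junb and Nr4a1 were the others. In both the Fcer2a and the Fcrl5 cluster, 7 of the 8 higher genes and 11 of the 11 lower genes with a finite ratio in both lay on the same side of 1 as in all B-like cells. The genes were ranked on their ratio over all B-like cells, most of which lie in these clusters, so this count is no separate check. Several intervals in the Fcer2a cluster included 1, such as Nr4a1 (0.247 to 1.45), Vpreb3 (0.744 to 1.24) and Isg15 (0.685 to 4.67).

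In NK-like cells the first genes ranked higher in the knockout were Gzmf at 3.68, with 2321 of 2830 knockout UMIs in 1 cell, the opioid precursor Penk at 4.20, from 2 cells per library, and Ifi27l2a at 2.59 (2.17 to 3.11). The others were Gzmg at 1.71, the cell cycle inhibitor Cdkn1a at 2.28, Cpsf3 at 1.97, Os9 at 1.59, Rgs2 at 2.21, Tmprss6 at 1.91, Cuedc1 at 1.98, Mtmr12 at 2.45 and the receptor gene Klra7 at 1.38. Gzmg was found in 13 control and 17 knockout cells, with 747 of its 1790 knockout UMIs in 1 cell. Lower were the chemokine gene Ccl1 at 0.0730, the interferon-induced Ifitm3 at 0.411 (0.364 to 0.464), Ifitm2 at 0.518 and Ifit3 at 0.444, and the immediate early gene Egr1 at 0.398 (0.291 to 0.540). Only 6 cells per library held Ccl1, with 253 UMIs in the control and 22 in the knockout. Rgs16 was at 0.451, Rnaseh2b at 0.405, the sterol synthesis genes Fdps and Msmo1 at 0.467 and 0.444, Mt1 at 0.487, Tsc22d1 at 0.426 and Tmem38b at 0.363. Gzmf was the 1 gene named in both classes. The median absolute log2 ratio over genes with at least 50 UMIs was 0.21 in B-like and 0.16 in NK-like cells. B-like cells held 924908 UMIs in the control and 1006215 in the knockout, against 1847609 and 2200532 in NK-like cells. Fewer UMIs raise this value through counting error, and the B-like value also carries the difference in cluster makeup. The 2 values therefore do not compare the size of the genotype difference.

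Among immunoglobulin constant genes in B-like cells, Igha was at 4.87 (3.51 to 6.88), Ighg3 at 5.40, Ighg2c at 2.19, Ighg2b at 1.87 and Ighm at 1.14 in the knockout relative to the control, and Ighd at 0.732. Ighg1 had 23 UMIs in the control and 0 in the knockout. These values also carry the difference in cluster makeup. In the V(D)J libraries, all 6 control and 28 of 29 knockout switched B-like heavy chains lay in the Fcrl5 cluster. All 10 control and 13 of 15 knockout IgD calls of B-like cells lay in the Fcer2a cluster. Few cells were involved, with 10 IgA and 3 IgG3 knockout and 2 IgG1 control B-like cells called. The light-chain genes Igkc, Iglc1, Iglc2 and Iglc3 were at 1.09, 1.99, 1.10 and 1.24.

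The V(D)J libraries gave a productive heavy chain in 135 control and 301 knockout cells. Recovery differed greatly between the genotypes: a heavy chain was found in 88 of 239 control B-like cells (36.8%, 30.7 to 43.3%) and in 273 of 287 knockout B-like cells (95.1%, 92.0 to 97.3%), and in 45 of 47 control plasma-like cells. Plasma-like cells held 97.7% of the contig reads of the control. Contigs of B-like cells had 3.25 reads per UMI in the control and 161 in the knockout. The control receptor values below therefore come from a part of its B-like cells, and not an even one. Recovery was 30.8% in the Fcer2a and 65.3% in the Fcrl5 cluster of the control, against 96.4% and 94.0% in the knockout. Control cells of the Fcrl5 cluster with a heavy chain had a median of 188 immunoglobulin UMIs, and those without had 75, so control shares over B-like cells weigh the Fcrl5 cluster and cells rich in immunoglobulin RNA more heavily.

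Class-switched heavy chains were found in 50 of 121 control cells with a called constant gene (41.3%, 32.4 to 50.6%) and in 36 of 301 knockout cells (12.0%, 8.52 to 16.2%). The control cells were 61 IgM (50.4%), 41 IgA (33.9%), 10 IgD (8.26%), 4 IgG2c, 3 IgG1 and 2 IgG2b, with 14 further cells lacking a call. The knockout cells were 250 IgM (83.1%), 15 IgD (4.98%), 14 IgG2b (4.65%), 13 IgA (4.32%), 6 IgG2c and 3 IgG3. All 41 control IgA cells were plasma-like, where IgA made up 93.2% of 44 called cells (81.3 to 98.6%). Within the B-like cells the switched share was 7.89% in the control (6 of 76, 2.95 to 16.4%) and 10.6% in the knockout (29 of 273, 7.23 to 14.9%). Within the Fcrl5 cluster it was 20% (6 of 30, 7.71 to 38.6%) and 17.7% (28 of 158, 12.1 to 24.6%), so no difference was detectable outside the plasma-like cells. IgA was found in 0 of 30 control cells of that cluster and in 10 of 158 knockout cells (6.33%, 3.08 to 11.3%). By the limit of 3 counts the control value allows up to 10.0%, and its Clopper-Pearson upper bound was 11.6%.

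**Figure D3:**
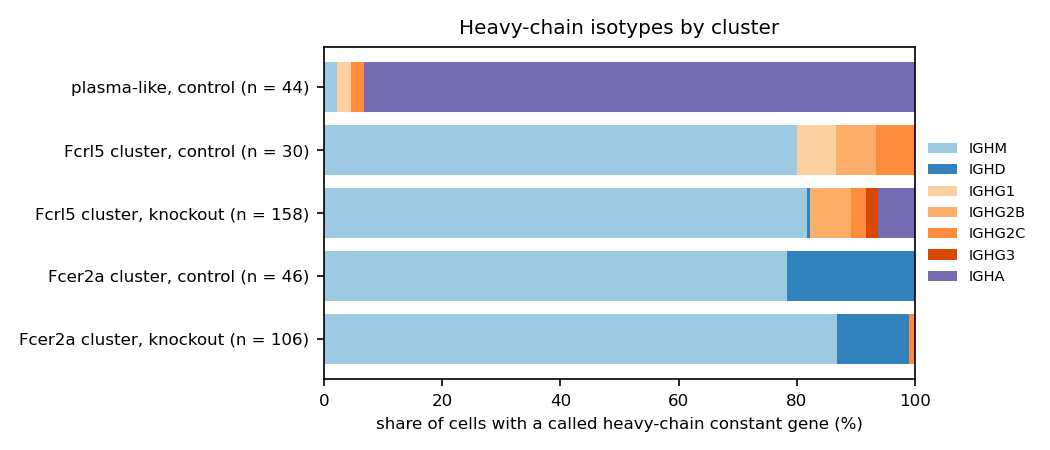
Share of cells (%, x axis) carrying each heavy-chain constant gene, by cluster and genotype, over cells with a called constant gene (n in the axis labels). IgA makes up 93.2% of the control plasma-like cells, and IgM 80.0% and 81.6% of the Fcrl5 cluster in control and knockout.

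Expanded clones made up a larger share of the knockout V(D)J library, with overlapping ranges within the Fcrl5 cluster. Thinned to 135 cells, 9.58% of knockout cells lay in a clone of 2 or more cells (5.19 to 14.8% over the draws), and 2.22% of control cells did (3 of 135, 0.461 to 6.36%), so the ranges meet. The range over the draws is not a counting interval, so whether the 2 ranges meet decides nothing. The counting intervals of clone shares treat cells of 1 clone as separate ones and are therefore too narrow. Unthinned, the knockout share was 13.3% (40 of 301, 9.67 to 17.7%). Within the B-like cells the shares were 3.41% in the control and 8.39% in the thinned knockout (2.27 to 14.8%). Within the Fcrl5 cluster, where most cells of expanded clones lay, they were 9.38% (3 of 32, 1.98 to 25.02%) and 11.5% (0 to 25% over the draws), or 22.2% unthinned (35 of 158, 15.9 to 29.4%), so the ranges overlapped. The biggest knockout clone had 14 cells with IGHV6-3 and IGHJ3 and the CDR3 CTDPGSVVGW, followed by 4 cells with IGHV1-69 and IGHJ2, and by 3 cells each with IGHV1-58 and with IGHV1-9. All of these were IgM, and 13 of the 14 lay in the Fcrl5 cluster. The only control clone of more than 1 cell had 3 IgM cells with IGHV6-3 and IGHJ2, all in the Fcrl5 cluster. No clone in the Fcer2a cluster had more than 1 cell there in either genotype, each of the 45 control plasma-like heavy chains was its own clone, and 0 clones were shared between genotypes. By cells, the commonest V genes were IGHV3-6 (5.93%), IGHV1-53 (5.93%) and IGHV1-26 (5.19%) in the control, and IGHV6-3 (8.97%), IGHV1-9 (5.98%) and IGHV1-26 (4.98%) in the knockout. By clones, knockout IGHV6-3 was not the commonest, with 13 of 273 clones against 14 each for IGHV1-9, IGHV1-26 and IGHV1-53.

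Mutated heavy chains, with 2 or more base differences from the inferred germline, made up 43.3% of control cells (39 of 90, 32.9 to 54.2%) and 32.9% of knockout cells (73 of 222, 26.7 to 39.5%). They were 79.3% of the control plasma-like cells (23 of 29, 60.3 to 92.0%). The Fcer2a cluster had 0 of 35 mutated cells in the control and 3 of 71 in the knockout (4.23%), and the Fcrl5 cluster 60.0% (15 of 25, 38.7 to 78.9%) and 51.2% (64 of 125, 42.1 to 60.2%). The 14-cell knockout clone supplied the commonest IGHV6-3 sequence and so counted as mostly unmutated. With each clone counted once in the inference, chosen after this was seen, only the IGHV6-3 sequence changed, by 9 bases. The shares then became 41.1% and 34.2% of all cells, 0 of 35 and 0 of 71 in the Fcer2a cluster, and 52.0% and 56.0% in the Fcrl5 cluster.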

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

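The tests of CD138+ cell input and of the V(D)J reads were chosen after the results they address had been seen. Genotype and library batch are confounded throughout, so a batch difference stays open for every pattern here.

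Some genes moved in opposite directions in the 2 large B-like clusters, each with a counting interval on its own side of 1. The difference between the clusters was not tested. Knockout over control ratios in the Fcer2a and Fcrl5 clusters were 1.60 and 0.638 for Ifi27l2a, 1.49 and 0.869 for Ly6a, 1.27 and 0.877 for B2m, 1.25 and 0.749 for Hsp90ab1, and 0.929 and 1.03 for Cd74. Ifi27l2a and Ly6a belong to the interferon list.

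The knockout library held 0 plasma-like cells against 47 in the control. Too few CD138+ cells entering the knockout library would lower other cells rich in Sdc1, the CD138 gene. A ratio of 0.0589 or less, set by the limit of 3 counts, would be needed to account for the whole loss. Over the 5 other clusters with an Sdc1 UMI in at least 25% of control cells, the share ratio was 0.459 (0.367 to 0.572), counting all of their cells. Cells with an Sdc1 UMI outside the plasma-like cluster were 17.3% of the control (130 of 751) and 5.09% of the knockout (44 of 865), a ratio of 0.294 (0.204 to 0.417), although the shallower knockout library would also lower that detection. The cluster led by Pmp22, with Sdc1 in 53 of 71 control cells, was at 0.221 (0.122 to 0.379), the macrophage- or monocyte-like cluster at 0.437 (0.299 to 0.629), a T-like cluster led by Tff1 at 0.426, a cluster led by Ace at 0.562 and the cluster led by Tcrg-V6 at 0.977 (0.594 to 1.61). None of these was as low as needed, but 3 of the 5 had an upper bound below 1, and RNA does not show which cells came through the CD138 gate. A smaller CD138+ input therefore stays open. A loss to shallow sequencing is argued against, since 0 of the 47 control cells would fall below the shallowest knockout barcode (508 UMIs) after scaling to the knockout depth. With 1 expression library per genotype, a difference between library batches cannot be told apart from the loss of Prdm1, which is the candidate explanation the design offers.

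Control B-like cells yielded a heavy chain far less often than knockout ones. Less immunoglobulin RNA in the control cells is argued against: among cells with at least 83 immunoglobulin UMIs in the expression library, 55.3% of control (52 of 94) and 96.6% of knockout B-like cells (142 of 147) had a heavy chain. Plasma-like cells held 97.7% of the control contig reads, which fits a loss of reads from B-like cells to them. The control contigs held 1186037 reads against 4132489 in the knockout, and 2.93 against 160 reads per UMI over all cells, plasma-like ones included, so fewer reads per molecule in the control library stays open beside it. Reads outside the contigs were not used here, and no biological explanation was tested.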

How the results depend on the processing

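Plasma-like, B-like and clone shares stayed within their intervals under the alternatives fixed before the data were examined, although 1 knockout cell was plasma-like without a barcode filter and 2 were with classes assigned cell by cell. Of all values those alternatives gave for the main comparisons, 80 stayed within the main interval and 6 did not. The Prdm1 level of control B-like cells went from 1.08 to 0 CPM at Leiden resolution 2.0, and with classes assigned cell by cell. The plasma cell and secretion median of 0.18 kept its sign but dropped to 0.00519 at Leiden resolution 2.0, 0.0280 as a mean over cells, 0.0622 with classes assigned cell by cell, 0.0896 with the stricter barcode filter and 0.0933 over members with at least 50 UMIs, so it was not robust. The MHC class II median of -0.16 became -0.24 with classes assigned cell by cell, -0.11 with CPM over other than immunoglobulin, mitochondrial and ribosomal genes, and -0.10 when centred on all genes. The knockout share of mutated cells fell to 25.7% at 4 or more differences, a stricter cut by construction. Among the alternatives chosen after seeing the data, the Prdm1 level was 0 CPM without the cell holding its 1 UMI, the MHC class II median was -0.0883 in the Fcer2a and -0.0241 in the Fcrl5 cluster, and the secretion median was -0.0500 in the Fcer2a cluster. B-like cells alone gave a control switched share of 7.89% and a mutated share of 25%, since plasma-like cells were left out. Without the top cell, the Ccl4 log2 ratio of -4.13 turned to 0.36, and Hbb-bs had no UMI left and gives no value. Otherwise the cause was not tested. No paired analysis was possible because each genotype has 1 library and no result comes from a test. Depth limits the Prdm1 comparison and the control isotype and mutation shares.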

Other observations

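The tests of Jchain in IgA cells and of shared light chains were written before their results were seen, but the patterns came from the same data and the limit of 5 Jchain UMIs was set after the values had been seen.

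The 2 large B-like clusters differed in their receptors in both genotypes, although immunoglobulin genes took no part in the clustering. In the Fcer2a cluster the IgD call was found in 21.7% of control and 12.3% of knockout cells, and in the Fcrl5 cluster in 0% and 0.633%. With each clone counted once in the germline inference, 0% of cells were mutated in the Fcer2a cluster of either genotype. In the Fcrl5 cluster, 57.1% of control and 55.5% of knockout IgM and IgD cells were mutated (12 of 21 and 61 of 110). The control plasma-like IgA cells carried a median of 8 base differences on that germline, and 1 plasma-like cell was IgM.

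The knockout library held 13 IgA cells but no plasma-like cells. A hypothesis is that these cells had begun the plasma cell programme without completing it. Jchain at 5 or more UMIs was found in 38.5% of them (5 of 13, 13.9 to 68.4%) and in 0.347% of the other 288 knockout cells with a heavy chain (0.00879 to 1.92%), which is consistent with it. Of the 13, 10 were B-like, with at most 80 Jchain UMIs, and 3 of these 10 held 5 or more. Another 2 were cycling cells with 48 and 66, and 1 had been removed by the filters. The 2 cycling cells belonged to 1 IGHV1-26 clone, so the interval above counts related cells as separate ones. Every control plasma-like cell held at least 291. None of the 13 had an Sdc1 UMI. Prdm1 UMIs did not follow the same split, being found in 1 of the 13 IgA cells and 15 of the 288 others. IgA B-like cells were too few in the control (0 of 76) to compare.

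A group of 11 knockout IgM cells, all in the Fcrl5 cluster, used IGHV1-9 and IGHJ2 with CDR3 sequences of 42 bases that differed by at most 15% from a neighbour. They held 7 distinct CDR3 sequences and 9 distinct V sequences, with 3 to 18 differences from the inferred germline. All 11 (100%) paired with IGKV5-39 with the same J gene and light-chain CDR3 length, which is consistent with a single lineage that diversified by mutation. Separate cells selected for the same receptor would also share these features, and the pooling of 11 recipients leaves that open. The clone of 14 IGHV6-3 cells had 5 distinct V sequences.

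Ighm was found without matching light chain in NK-like cells, at 134 CPM in the control and 175 CPM in the knockout, where Igkc stood at 7.58 and 5.45 CPM. In B-like cells Ighm stood at 958 and 1094 CPM and Igkc at 1419 and 1542 CPM. A single source of free RNA would keep 1 ratio, so these UMIs do not look like free RNA from B-like cells. In plasmacytoid dendritic-like cells Ighm was at 565 and 771 CPM. Light-chain levels are not given here for those cells, so the argument above covers NK-like cells only. Heavy-chain contigs were found in 6 of 43 knockout T-like cells (14.0%, 5.30 to 27.9%) and in 0 of 34 control ones, and in 6 of 38 knockout and 0 of 27 control cycling cells. The B cell gene Cd79a was found in 7 of the knockout T-like cells (82 UMIs) and in 2 control ones, and Ms4a1 in 6 and 2, so barcodes holding more than 1 cell were not excluded there.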
